A study of Oryzias latipes with 6 samples.

How the data were processed

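Gill RNA of Japanese medaka was measured on 6 custom oligonucleotide arrays with 1 dye, cyanine 3, per the labels. The labels placed 3 samples in freshwater and 3 in water of high carbonate alkalinity, all taken at 96 h. Total RNA was extracted with Trizol, checked for integrity and treated with DNase, and labelled complementary RNA was made by linear amplification, per the labels' protocols. Whether the replicates were separate fish or pools of fish was not given in the sources used here, so the p-values measured only the spread between these samples, which may be partly technical.

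The processed signal of each spot was an intensity that the authors' scanning software had corrected for background and for gradients across the array and had not scaled between arrays, per the file headers. Spots near background carried a surrogate value set by that software in place of a negative or very small one, per the file headers. The mean signal and the local background of each spot were also deposited as intensity. The software was Agilent Feature Extraction 10.5.1.1, per the file headers, whereas version 9.1 was named per the submitters' processing notes. A second table held deposited log2 values per probe. Its 6 columns had nearly the same distribution, with quantiles that differed by at most 0.00084 and a median of 10.06 in each array. Each column correlated with the log2 processed signal of its own array at r of at least 0.99967, against at most 0.989 with any other array, across probes. The method by which the authors made that table was not given in the sources used here.

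Each array held 43277 spots that were not controls, for 26429 probes of 60 bases. Of these probes, 22407 were spotted once, 4014 were spotted 5 times and 8 were spotted 100 times. The files used here did not pair the probes with genes, since every description read as unknown and every position as unmapped. The probes held 26007 distinct sequences, and 779 probes shared their whole sequence with another probe. Gene names, genomic positions and transcript annotation were therefore not used here, and the gene-level tests, the tests of gene lists and the cell type markers that had been planned could not be made. Probes with similar sequence were found by aligning the probes to each other with blastn 2.17.0 (at least 30 bases at 90% identity or more).

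Processed signals were log2-transformed, and the 75th percentile of the non-control spots of each array was subtracted. Spots marked by the software as non-uniform or as population outliers were left out, between 313 and 394 per array, and the remaining spots of a probe were averaged. A probe was taken as well above background on an array when at least 50% of its spots were marked so. Probes well above background on at least 3 of the 6 arrays were tested, whatever their group, which kept 24517 probes and left out 1912. Among the tested probes, 60 lacked a value on at least 1 array. Alkaline water was compared with freshwater by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Where a changed probe was below background on a freshwater array, its fold was given as a lower bound, for which that array entered with the higher of its value and the lowest value called well above background on it. Such a bound holds only for the background correction of the scanning software.

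No count of molecules underlies an array signal, and the number of arrays limited the precision. The procedure was tested on simulated data in 10 runs of 24457 probes, with 50 probes changed at each of 4 sizes. The values were independent and normal, with the spread of each probe set to limma's moderated estimate from these arrays. The procedure recovered 34.2% of the probes changed 2-fold, 89.8% of those changed 4-fold, 94.8% at 8-fold and 97.4% at 16-fold, with a mean of 7.6 false calls per run. The simulation held no slide or sample structure and no background floor, and 200 probes changed in each run. Its percentages therefore need not hold for the real arrays.

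The test, the filter on dim probes and most alternatives were fixed before the data were examined. These covered background correction by normexp (offset 50), quantile and median scaling, other filters on dim probes, an intensity trend, array weights, the replicate number or the slide as a term, the deposited log2 values, an unmoderated two-sample test, and leaving out each array. Alternatives chosen after the data were seen were the arrays of slide 1 alone, a smooth correction for probe GC content, each distinct sequence counted once, and outlier spots kept. The rule for named items asked for gene symbols, so no gene qualified. The probes named instead were the 2 highest fold changes and, in the other direction, the only changed probe, among changed probes whose groups did not overlap. That number per direction was chosen after the gene names were found missing. The groups of 3 were too small for a test of single outlying samples.

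The file headers placed the 6 arrays on 2 slides. Slide 1 held the 3 freshwater arrays and alkaline water array 1, and slide 2 held alkaline water arrays 2 and 3. With the slide as a term, the fit therefore compared freshwater with alkaline water array 1 alone and took the spread from both slides.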

Results

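The series measured RNA in the gill of Japanese medaka (Oryzias latipes), a small fish used widely as a laboratory model. The gill is the organ through which a fish exchanges gases, moves ions, regulates its acid-base balance and excretes ammonia. Fish were held for 96 h in freshwater or in water of high carbonate alkalinity, that is, water rich in dissolved bicarbonate and carbonate. The pH and alkalinity of both waters were not given in the sources used here. Each group had 3 arrays, written here as FW1 to FW3 for freshwater and AW1 to AW3 for alkaline water. The median processed signal lay between 1362 and 1792 intensity units per array, and no spot was saturated. Between 91.4% and 93.2% of the 26429 probes were well above background on each array.

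Whole profiles of the 6 arrays were close to each other, and the 2 groups were only slightly farther apart than the arrays within a group. Across probes, the mean correlation was r = 0.984 between freshwater arrays, 0.980 between alkaline water arrays and 0.977 between the groups. The ranges overlapped, since pairs from different groups reached 0.983 and the lowest pair within alkaline water had 0.974. Array AW1 had the lowest mean correlation with the other arrays, 0.973. For every pair of arrays, the differences between them were at least 4.05 times as wide as the scatter of repeated spots would give over 3773 probes, so no pair of arrays agreed within spot scatter. This does not show whether the arrays held RNA of separate fish, since repeat labellings of one RNA would also exceed the scatter of spots.

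**Figure D1:**
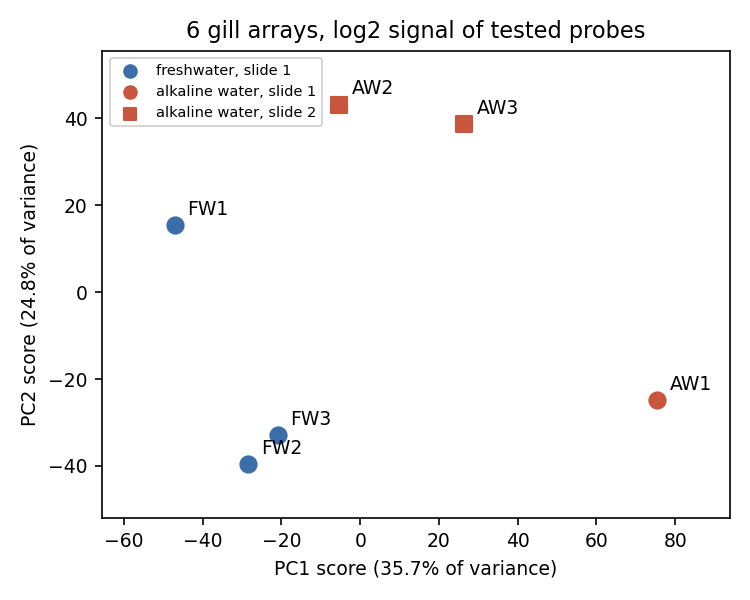
Principal component scores of the 6 arrays, computed from the log2 signal of the tested probes, with PC1 (35.7% of variance) on the horizontal and PC2 (24.8%) on the vertical axis. Blue marks freshwater, red marks alkaline water, circles mark slide 1 and squares mark slide 2. FW1, FW2 and FW3 had PC1 scores of -47.09, -28.43 and -20.97, all lower than those of AW2 (-5.33), AW3 (26.35) and AW1 (75.46).

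The comparison of alkaline water with freshwater asked how gill transcripts respond to alkalinity stress. After 96 h, a small set of probes stood far above their freshwater level, and most of the array moved little. In limma, 15 of the 24517 tested probes changed, of which 14 rose and 1 fell in alkaline water. Among the 14 that rose, 11 were above background on every freshwater array, 1 on a single freshwater array and 2 on none. With the latter 3 probes entered at lower bounds of 7.33-fold, 2.76-fold and 6.53-fold, the median rise was 8.97-fold and 7 of the 14 probes rose at least 8-fold. The smallest rise was 2.48-fold. These sizes depended on the background correction in dim probes. With normexp, which compresses dim signals, the same 14 probes had a median rise of 6.21-fold, 6 of them rose at least 8-fold, and 3 that were not above background on all freshwater arrays were 1.29-fold to 1.91-fold higher and did not pass the threshold. In each of the 15 probes, all 3 alkaline water arrays lay on the same side of all 3 freshwater arrays. The files used here did not pair the probes with genes or with positions in the genome, so the changed probes are given by identifier and sequence.

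The changed probe with the highest fold change, CUST_4214_PI414333748, rose 85.8-fold (log2 fold change 6.42, SE 0.23, limma adjusted p = 0.00115). Its log2 signal relative to the 75th percentile of the array was -6.96 ± 0.18 in freshwater and -0.54 ± 0.39 in alkaline water (SD, n = 3 each). Its mean intensity went from 59.9 units in freshwater, a dim spot, to 5419 units in alkaline water. Its sequence was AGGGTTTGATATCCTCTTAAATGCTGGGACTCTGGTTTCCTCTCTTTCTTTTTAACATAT, with a GC content of 36.7%. It passed the threshold in 20 of 21 alternative settings, with log2 fold changes from 5.17 to 6.69, and missed it in the unmoderated two-sample test. The lowest of these came from normexp background correction, which acts most on dim spots such as its freshwater ones.

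CUST_8260_PI414333748 rose 64.9-fold (log2 fold change 6.02, SE 0.53, limma adjusted p = 0.0376). Its scaled log2 signal was -8.25 ± 0.52 in freshwater and -2.23 ± 1.02 in alkaline water (SD, n = 3 each), and its mean intensity was 25.3 and 2005 units. Its sequence was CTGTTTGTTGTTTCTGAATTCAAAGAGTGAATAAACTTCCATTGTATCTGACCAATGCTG (GC 35%). Its rise was less uniform, with a log2 difference from freshwater of 4.92 in AW1 and 6.57 in the mean of AW2 and AW3. With normexp background correction the log2 fold change was 4.06, and over 21 settings the probe passed the threshold in 13, with adjusted p from 0.00958 to 0.269.

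CUST_23581_PI414333748 was the only probe that fell. Its log2 signal fell by 1.83 (SE 0.18, limma adjusted p = 0.0466), from 4.21 ± 0.18 in freshwater to 2.37 ± 0.24 in alkaline water (SD, n = 3 each). This was a bright probe, with a mean intensity of 136526 units in freshwater and 41420 units in alkaline water. Its sequence was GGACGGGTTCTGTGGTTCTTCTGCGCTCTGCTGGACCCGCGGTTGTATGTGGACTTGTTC (GC 58.3%). It passed the threshold in 10 of 21 settings, with adjusted p from 0.0151 to 0.238, and its log2 fold change stayed between -2.01 and -1.75.

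The other 12 changed probes all rose. A pair of them shared 93.8% of 48 aligned bases and rose by similar amounts, 14.9-fold and 16.5-fold. Of all 14 probes that rose, 11 were well above background on all 6 arrays, so their rise was measured between 2 detected levels. In a further probe the freshwater signal was above background on some arrays only. Of the 15 changed probes, 3 were spotted 5 times on each array, and the rest once.

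**Figure D2:**
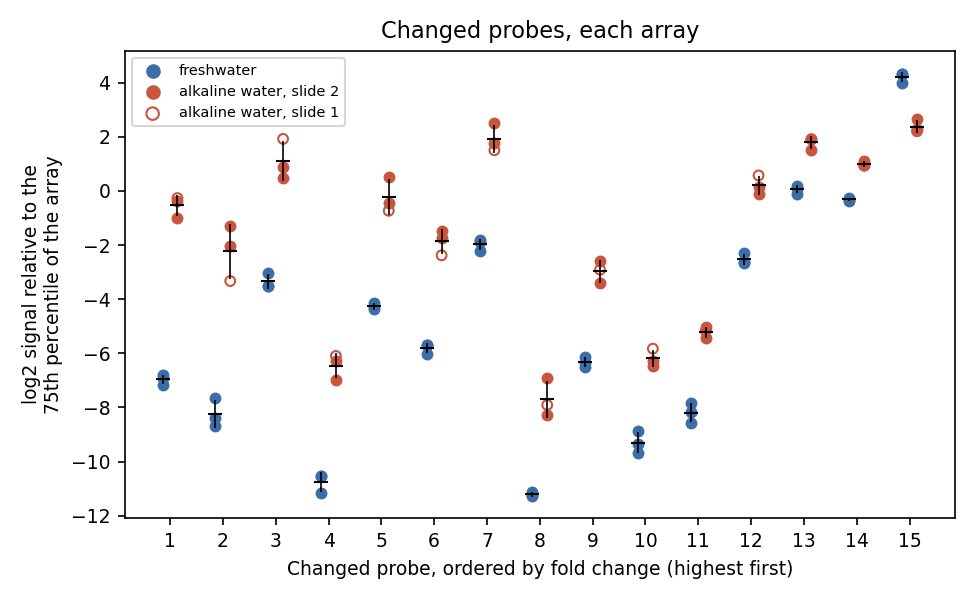
Log2 signal relative to the 75th percentile of the array (vertical axis) for the 15 changed probes, ordered by fold change from the highest to the lowest (horizontal axis). Points are single arrays, with freshwater in blue, alkaline water on slide 2 in filled red and alkaline water on slide 1 in open red, and black marks show the mean with SD of the 3 arrays of a group. In 14 probes all alkaline water points lie above the freshwater points, and in the 1 that fell they lie below.

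Most other probes differed little between the groups. The median absolute log2 difference over all tested probes was 0.21, against a median SD of 0.18 within freshwater and 0.24 within alkaline water. At an unadjusted p under 0.05, limma gave 3080 probes (12.6%, with 1226 expected if nothing changed), 1791 higher and 1289 lower in alkaline water. This balance depended on the scaling, with 1444 higher and 1720 lower after quantile scaling, 1347 and 1812 after normexp correction, and 1447 and 1734 in the deposited log2 values. When the arrays were split instead into equal groups that each held both waters, limma gave from 346 to 1882 probes at that threshold. A count above 1226 can therefore arise without a split by water, and the excess over 1226 is not by itself evidence of an effect of the water. Groups did not overlap in 4961 probes (20.2%), where chance gives 10%. The means were at least 2-fold apart in 853 probes, of which 553 were higher and 300 lower, and 525 of the 853 had an unadjusted p under 0.05, of which 510 did not pass the adjusted threshold. In 19 probes that did not pass it, every alkaline water array was still at least 4-fold above every freshwater array. Freshwater signals below background entered this count at their values, not as bounds. CUST_10262_PI414333748, for example, was above background on no freshwater array. The others of the 853 probes differed by 2-fold or more in the mean with a spread between arrays too wide for an unadjusted p under 0.05.

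**Figure D3:**
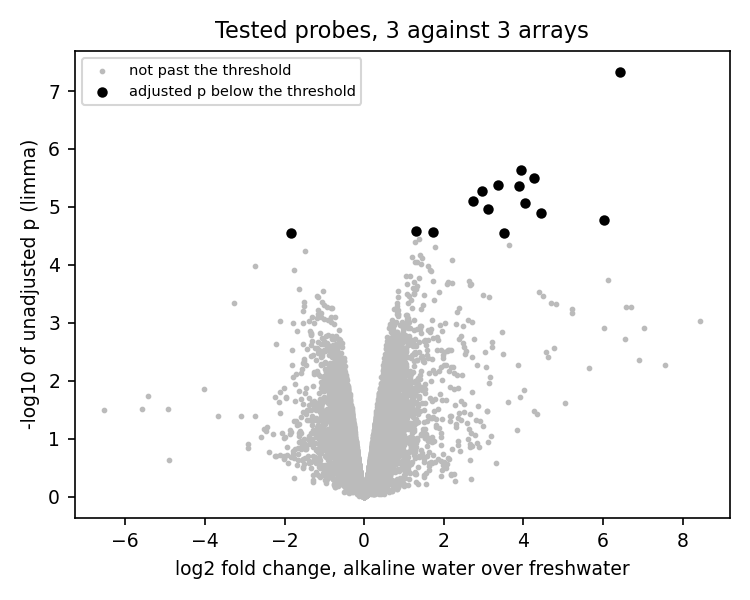
Each point is 1 of the 24517 tested probes, with the log2 fold change of alkaline water over freshwater on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Black points are the 15 probes past the adjusted threshold, of which 14 lie to the right of 0 and 1 to the left.

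Slide and group overlapped in part, because slide 2 held alkaline water arrays only. Within slide 1, AW1 differed from the freshwater mean in the same direction as the whole group for all 15 changed probes, with a median log2 difference of 3.44 over the 14 that rose, and the same median was 3.82 for AW2 and AW3 on slide 2. AW1 had itself entered the choice of these probes. With the slide as a term, limma called 211 probes, 119 higher and 92 lower, and 13 of the 15 were among them. With the arrays of slide 1 alone, it called 21 probes, 9 higher and 12 lower, and 4 of the 15 were among them. The count of changed probes was 4, 1 and 2 without FW1, FW2 and FW3, and 18, 12 and 3 without AW1, AW2 and AW3. It was 26 with an intensity trend, 90 with array weights and 0 in an unmoderated two-sample test, in which 2669 probes had an unadjusted p under 0.05 and limma's moderated test on the same values gave 15 changed probes.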

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

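Over 21 other settings, the 15 changed probes kept their direction wherever they were tested, and the count stayed between 12 and 21 in 12 of the settings. The direction had little room to turn, since the groups did not overlap in any of the 15 and all settings used the same arrays. A similar count was not always the same set, since 8 of the 15 were kept without AW1 and 4 without AW2. Alternatives chosen after the data were seen were slide 1 alone, GC correction, distinct sequences and kept outlier spots. The count was 21 with normexp correction (20 higher, 12 of the 15 kept, adjusted p up to 0.448), under which the log2 fold changes of the 15 were a median of 0.847 and as little as 0.106 times the reported ones. It was 15 with quantile scaling (14 kept), 16 with median scaling, 17 in the deposited log2 values, 12 with no filter, 14 with probes above background on all 6 arrays, 14 after GC correction (13 kept), and 15 with distinct sequences or kept outlier spots.

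It moved to 26 with an intensity trend, to 90 with array weights (79 higher, 11 lower) and to 211 with the slide as a term (119 higher, 92 lower), and the cause was not tested. The unmoderated two-sample test gave 0 changed probes and 2669 at an unadjusted p under 0.05, where limma gave 15, with the spread of each probe taken from 4 degrees of freedom alone. Slide 1 alone gave 21 (9 higher, 12 lower, 4 of the 15 kept). Leaving out 1 array gave from 1 to 18 probes, namely 4, 1 and 2 without FW1, FW2 and FW3, and 18, 12 and 3 without AW1, AW2 and AW3. Between 1 and 8 of the 15 were called each time, while the median ratio of their log2 fold changes to those from all arrays was 0.981 to 1.01, with 0.889 the lowest for a single probe. Without AW2 the split was 7 higher and 5 lower.

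With the replicate number as a replicate block the count was 4, of which 1 was among the 15. Deviations of same-numbered arrays correlated at r = -0.186, -0.127 and 0.015 across probes, so the values showed no pairing by number. With so few arrays per group this cannot exclude a pairing. Signal over background limited the folds of 3 probes to lower bounds (2.76, 6.53 and 7.33), which normexp did not keep. The gene-level and gene-list results were not run under any setting because the probes carried no gene names.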

Other observations

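The tests of the splits, of the 4-fold gaps, of scaling and near-background signal, of the slide as the whole cause, of each slide 1 array left out, of GC correction in the 15 changed probes, and of the slide for AW1 were chosen after the data or the results were seen, while those of AW1 left out, spot noise and GC content for AW1, individual differences and shared sequence were set before their results were seen. There were 52 probes well above background on all 3 alkaline water arrays and on no freshwater array, against 6 with the reverse. The lower bound of the fold had a median of 1.49 in the 52 and 2.17 in the 6, reached 2-fold in 12 and 4 of them, and was highest at 23.4-fold and 2.52-fold. Of the 52, 2 passed the adjusted threshold in limma. Some control types went the same way, since 2 of the 60 control types were above background on all alkaline water and no freshwater arrays, 0 showed the reverse, and the 8 control types at an unadjusted p under 0.05 were all higher in alkaline water (lowest limma adjusted p = 0.137). The 33 control types below background on all arrays did not go that way as a set, with 14 higher and a median log2 shift of -0.06. Those above background on at least 1 array mostly did, with GE_BrightCorner and DCP_22_9 the only ones lower. The controls thus left open whether the 52 against 6 reflects the gill or the background. The arrays also differed by group, AW1 included. Probes well above background numbered 24403 to 24632 per alkaline water array and 24154 to 24299 per freshwater array. Spots with a surrogate value numbered 761 to 821 and 868 to 1041. The median SD of repeated spots was 0.0512 to 0.0559 and 0.0667 to 0.0744 in log2. The cause of these differences was not tested. The 8 probes spotted 100 times were bright, with a median scaled log2 signal of 3.70, and none changed (log2 fold changes from -0.36 to 0.55, lowest limma adjusted p = 0.344), with 2 at an unadjusted p under 0.05.

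Probes with related sequence moved together. Over 502 pairs of probes with identical sequence, log2 fold changes correlated at r = 0.974 across pairs, with a median difference of 0.04, and over 1324 pairs with similar sequence on the same strand at r = 0.895. Over 89 pairs on opposite strands, the correlation was 0.187. A candidate explanation for the changed pair that rose 14.9-fold and 16.5-fold is therefore that both probes read the same transcript or close relatives, as the value of 0.895 over similar pairs would give. The 15 changed probes may then stand for fewer than 15 genes. Pairs are not independent replicates, and 2 other changed probes had a similar partner that did not pass the threshold. Both partners had a positive log2 fold change too, 4.83 beside 4.28 and 1.96 beside 3.51. These 2 changed probes were above background on no freshwater array.

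The set of 15 changed probes was weighed first. The 10 splits of the 6 arrays are too few for a share under 0.05, and the split by water gave 15 changed probes, as 1 of 10 splits, against 3 in the highest other. A smooth trend with probe GC content as the cause was argued against. After its removal, 100% of the changed probes kept their log2 fold change, at 0.983 times the uncorrected value or more. The 2 that no longer passed went from 1.73 (SE 0.17) to 1.70 (SE 0.19) and from 1.31 (SE 0.12) to 1.29 (SE 0.13), with a wider spread. The correction moves probes of like GC content together, so it could not show an effect of GC content on single probes. The slide as the whole cause could not be decided from the 15 probes, because AW1 had entered their choice. AW1 differed from the freshwater arrays of its own slide in the same direction in all 15. The slide term left their log2 fold changes at a median of 1.02 times the reported ones (lowest 0.817), with 13 of the 15 called. That ratio rests on the same difference of AW1 from freshwater. Whether the slide caused or added to the differences stays open. In 18 probes called without AW1, AW1 lay beyond the freshwater range on the side of AW2 and AW3 in 15. Its difference was 0.610 times theirs (median, 95% bootstrap interval over probes 0.362 to 0.831). That interval holds no spread between arrays, since AW1 is a single array. When FW1 was left out instead, it too lay with slide 2 in 8 of 8 probes that parted the other slide 1 arrays from slide 2 (FW2 in 1 of 2, FW3 in 0 of 1). Over the top 50 probes of each such fit, past the threshold or not, this held for AW1 in 46, FW1 in 40, FW2 in 22 and FW3 in 25. Differences between individual samples also stay open, although the bound set before was met. There were 89 probes at a gap of at least 2-fold between the water groups and 70 between FW1, AW2, AW3 and FW2, FW3, AW1. The difference of 19 lay within 2 counting SDs of 12.6. That SD takes probes as independent, so it does not measure the spread of such counts between splits. The 4-fold gaps, looked at afterwards, were 31 by water and 44 by that other split. Gaps were counted with signals below background at their values. CUST_3350_PI414333748 was among the 31, with a bound of only 2.76-fold. These counts therefore cannot decide whether the samples held a structure that does not follow the water.

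The excess of probes that rose, 14 against 1, was weighed next. The share of higher probes among the changed ones was at least 0.875 under median and quantile scaling, normexp correction and the deposited values. These settings called 1 or 2 lower probes each. They also called 12 to 15 of the same 15 probes, whose groups did not overlap, so the share had little room to fall. It therefore cannot decide whether scaling added to the excess. Undetected freshwater signals did not account for most of the excess. When only the 23538 probes well above background on all 6 arrays were tested, 13 rose and 1 fell. Such signals were still more frequent among the probes that rose. A share of 0.786 of these was well above background on all 6 arrays, against 23538 of the 24517 tested probes. Freshwater signals near background may therefore add to the excess. The slide, single arrays and an effect of the water stay open, since the sets of probes called in some other fits were more even. There were 119 higher and 92 lower with the slide as a term, and 7 and 5 without AW2. Other sets stayed uneven, with 25 higher and 1 lower with an intensity trend, 79 and 11 with array weights, and 16 and 2 without AW1. A further excess of higher probes among the dimmest 20% of tested probes (512 higher against 172 lower at an unadjusted p under 0.05) may come from scaling or background correction, since the percentage of higher probes there went from 74.9 to 49 with quantile scaling and 45.6 in the deposited values, but it was 71.1 with median scaling. It was 13.4 with normexp, which also lowered the 33 control types below background (0 higher, median log2 shift -0.31). In the processing used these 33 showed no rise (14 higher, -0.06, against 0.13 in the dimmest probes), but they were chosen for lying below background. Of the control types above background on at least 1 array, all but GE_BrightCorner (-0.23) and DCP_22_9 (-0.04) were higher in alkaline water. A technical rise of dim signals therefore stays open.

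The distance of AW1 from the other arrays was the last pattern. The slide was left open, because the value at hand, a difference of -0.0025 between the highest correlation of AW1 with the freshwater arrays of its slide and the lowest between freshwater and slide 2, came from the correlations that showed the pattern and has no spread. Spot noise was argued against, since the SD of repeated spots on AW1 was 0.804 times the median of the other arrays, and probe GC content accounted for a share of 0.00623 of the variance of its deviations. A stronger or different response of the gill in that sample, another tissue composition and RNA quality stay open and untested, because without gene names no markers could be read. Without AW1, limma called 18 probes, of which 8 were among the 15.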
